A study of Mus musculus with 6 samples.

How the data were processed

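Cortex was dissected at postnatal day 0 from 3 Satb2 mutant and 3 wild type pups of heterozygous crosses, and total RNA of each brain was made into a TruSeq library and sequenced as paired ends of 50 nt on a Genome Analyzer II, per the labels' protocols. The genotype label of the mutants names a conditional knockout while the protocol describes homozygous mutants from heterozygous parents; they are called Satb2 mutants here. Bowtie, TopHat, DESeq and genome build mm9 are named in the submitters' processing notes, and DESeq was run to find genes that differ between genotypes, per the labels' protocols. Tool versions, the counting tool, its strand setting and the gene annotation are not given in the sources used here. The file holds a signal that the authors deposited as normalized counts: read counts per gene divided by 1 size factor per library, to 2 decimals, for 3900 rows (3876 symbols, with 48 rows sharing a symbol with another row). Coordinates are those of the file, whose header names mm9.

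Whole reads were recovered from the steps of the values. A read was worth between 1.50 and 1.75 normalized counts, and 100% of values in each of the 6 libraries came out whole within 0.05 reads. The size factors were 0.66, 0.573 and 0.595 for wild type replicates 1 to 3 and 0.667, 0.583 and 0.577 for mutant replicates 1 to 3. Reads on the listed rows numbered 6285193, 5565449 and 5284877 in the wild types and 5521689, 4841889 and 4626637 in the mutants; since the rows are a part of the genes, these totals are not library depth. Replicates of a group differed beyond counting noise (chi-square per degree of freedom between 8.95 and 69.0), so each library was counted as 1 replicate.

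The design fixed before the data were examined assumed whole-number counts or normalized values and named limma on log2(value + 1) for the latter, which was used. Rows with a mean of at least 10 normalized counts over the 6 libraries were kept (3858 rows; this limit was set after the file was seen). Genotype was tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, two-sided, Benjamini-Hochberg adjusted p under 0.05). Fold changes are on the log2(value + 1) scale, which understates changes of low genes. The adjustment covers the listed rows, which were chosen on the outcome. The 27 gene lists were fixed before the data were examined; a member with several rows was represented by the row with the highest mean. The 22 lists with at least 3 listed members were tested with camera (inter-gene correlation 0.01, two-sided, Benjamini-Hochberg over the lists), which compares a list with the other listed rows only, and again with the correlation estimated per list. None of the 7 lists called held with the estimated correlation.

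The genes named are Satb2; the 12 highest and 12 lowest by log2 fold change among rows past adjusted p 0.05, with no overlap between groups and a mean of at least 50, leaving out predicted genes; from each list up to 4 members past the threshold with the smallest adjusted p, or the 2 with the highest mean where fewer than 2 passed; and a fixed set of layer markers. Genes with near-identical copies, and the 357 rows whose span overlaps that of another row, may share reads, since how such reads were counted is not known.

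Of the alternatives listed before the data were examined, those run were DESeq2 and upper-quartile scaling of the recovered reads, pseudocounts of 0.1 and 10, no low-value filter and a stricter one (mean of at least 50 and a minimum share of the reads in at least 3 libraries), litter as a term, litter m2 only, each library left out, DESeq2 1.42.0, limma-voom and edgeR 4.0.16 with robust fitting on the recovered reads, a limit of 1.5-fold, scaling of Satb2 to the total of the listed rows, camera with an estimated correlation, fry, and lists without shared members. Added after the data were seen were edgeR quasi-likelihood tests on the recovered reads with the submitters' size factors, with and without litter, TMM scaling, an adjustment over 55450 annotated genes, Fisher's exact test of list direction, camera with an estimated correlation and litter as a term, and the count of rows for litter itself. The edgeR test on the recovered reads called 3445 rows. Transcript length and GC content came from GENCODE M21 by symbol, with no coordinates taken from it.

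The tests were run on simulated reads with the means and size factors of the real libraries, an assumed spread between replicates, and 200 of the rows changed by a known fold. For the comparison of mutant with wild type, with 3853 rows in the test, limma called 48% of rows changed 1.5-fold, 92% of those changed 2-fold and 100% of those changed 4-fold or 8-fold, and 0.274% of the unchanged rows. The simulation drew rows independently and without a litter effect, and changed few of them. The real rows had been chosen for change, so these rates do not carry over to them.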

Results

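RNA was sequenced from the cerebral cortex of 6 mouse pups at postnatal day 0, 3 of them Satb2 mutants and 3 wild type, with 1 library per brain. The labels differ on whether the mutants are homozygous or conditional knockouts. Satb2 encodes a DNA-binding protein of the cell nucleus that callosal projection neurons, which connect the cortical hemispheres, need for their identity. The values were normalized read counts for 3900 rows, each a gene with its position in mouse genome build mm9. The rows had been chosen for a difference between the genotypes: 92.4% of them had an unadjusted p under 0.05 in DESeq2 on the recovered reads, and the order of the rows followed that p (Spearman 0.80 across rows, which are not independent replicates). Counts of changed genes below therefore describe a chosen set, adjusted p-values do not give a false discovery rate over all genes, and genes outside the set were not analysed here. Between 4626637 and 6285193 reads per library fell on the listed rows, which is a part of each library and not its depth.

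Satb2 itself was measured first, as a check of the genotype labels. The gene, on chromosome 1 from 56850824 to 57028178 (mm9), had 41917, 49569 and 30451 normalized counts in wild type replicates 1, 2 and 3 and 2762, 2757 and 1960 in Satb2 mutant replicates 1, 2 and 3. The mean fell from 40646 ± 9622 to 2493 ± 462 (SD, n = 3 each), 16.2-fold on the log2(value + 1) scale (log2 fold change -4.02, SE 0.20, limma adjusted p = 1.09e-05). No mutant library overlapped a wild type library. Which part of the gene is altered was not given in the sources used here, so the remaining reads were not assigned to a part of it.

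The libraries separated by genotype along the first principal component, which held 80% of the variance of the listed rows. Those rows had been chosen for a genotype difference, so the separation is no independent result. Litter was the only batch given, and it was partly confounded with genotype: all 3 mutants and wild type replicate 3 came from litter m2, and wild type replicates 1 and 2 from litter m1. Wild type replicate 3 stood apart along the second component, with 11.3% of the variance. The SD of the log2 difference over rows was 0.33 between wild type replicates 1 and 2 and 0.64 between wild type replicates 1 and 3. For this reason the genotype difference within litter m2, from a fit with litter as a term, is given where it changed the call of a named gene. That within-litter value rests on 1 wild type library, which is assumed to vary like the libraries of the other groups. Counts of list members that rose or fell are from the pooled fit unless stated, and in many lists fewer members passed with litter as a term.

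**Figure D1:**
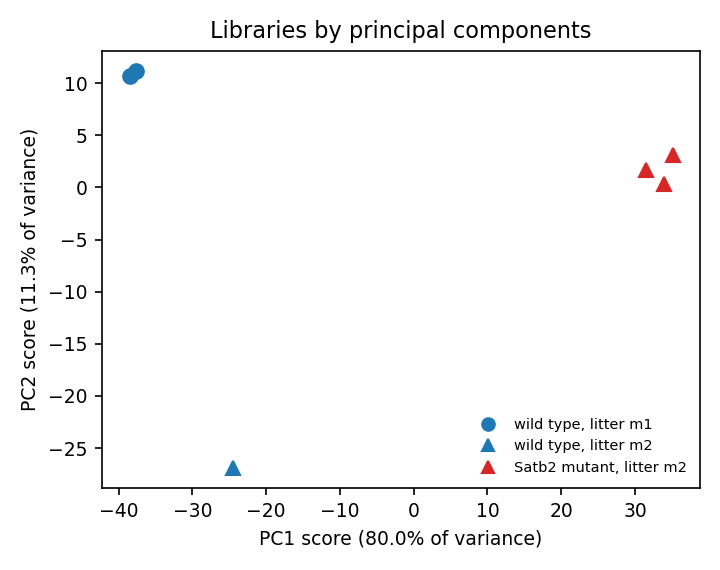
Scores of the 6 libraries on the first principal component (x axis, 80% of variance) and the second (y axis, 11.3% of variance) of the log2 values of all listed rows. These rows had been chosen for a genotype difference. Circles are wild type libraries of litter m1, blue triangles the wild type library of litter m2 and red triangles the mutants of litter m2; the mutants lie apart on the first axis and wild type replicate 3 on the second.

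The comparison of mutant with wild type cortex asked which genes change when Satb2 is lost. The largest falls after adjustment were in Msx3, a homeobox gene (66.2-fold, from 814 ± 59.7 to 12.8 ± 8.5 normalized counts, SD, n = 3 each), Hspb3, a small heat shock protein gene (44.9-fold), Grp, which encodes gastrin-releasing peptide (30.7-fold), Has2, a hyaluronan synthase gene (24.4-fold), and Klhl14 (21.8-fold). The inward-rectifier potassium channel gene Kcnj2 fell 17.2-fold, and Inhba, Unc5c, Ermn, Kcnh1 and Fst fell between 13.3-fold and 14.8-fold. The largest rises were in Cr2, a complement receptor gene (94.4-fold, from 20.0 ± 10.9 to 1815 ± 182), BC023719 (38.4-fold) and Nrp2, which encodes neuropilin-2, a semaphorin receptor (33.5-fold, from 310 ± 122 to 9950 ± 948). AK162965, Ankrd43, Cdhr1, Gcg, Lamc2, Scel, Ndst4, Spp1 and Atp6ap1l rose between 7.67-fold and 14.2-fold. In mm9, Cr2 lies on chromosome 1 from 196963004 to 197002909, Nrp2 on chromosome 1 from 62749890 to 62865266 and Msx3 on chromosome 7 from 147232055 to 147234987. All 24 of these genes, Satb2 among them, separated the groups without overlap, which was a condition for naming them. Their log2 fold changes kept their sign within litter m2. AK162965 and BC023719 differed strongly between wild types. The log2 difference of AK162965 was 3.59 between the litters and 1.43 between genotypes within litter m2. BC023719 had 36.3 and 24.4 normalized counts in litter m1 and 1.68 in wild type replicate 3, and its log2 fold change was 7.61 within litter m2 but 4.09 without that library, below that of Nrp2. Single wild types also moved the log2 fold changes of AK162965 (5.02 without replicate 3, 3.10 without replicate 2), BC023719 (5.99 without replicate 1), Gcg (4.33 without replicate 1), Atp6ap1l (2.30 without replicate 1) and Spp1 (3.73 without replicate 2).

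Of 3858 rows tested with limma, 3359 passed an adjusted p of 0.05, 1363 higher and 1996 lower in the mutants. The groups did not overlap in 82.6% of the 3900 rows. Chance gives 10% with 3 against 3 in rows not chosen on the groups, which is no reference for these. With litter as a term 2141 rows passed, 908 higher and 1233 lower, and 2056 of them were called in the same direction without it. Without mutant replicate 1 the number was 2184, and without wild type replicate 3 it was 3705. The share of called rows that were lower depended on the scaling: it was 59.4% with the submitters' size factors, 43.5% with TMM factors, 44.2% with upper-quartile factors and 33.9% with DESeq2 size factors, each of the last 3 computed from the listed rows alone. These shifted the median log2 fold change up by between 0.23 and 0.36. They take the listed rows as mostly unchanged, while the rows had been chosen for change. A modest fall can therefore lose its call below through the scaling alone, which does not decide whether the gene changed.

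Genes of callosal and upper-layer neurons were lower in the mutants. Of 30 genes in the list, 23 were among the rows, 22 fell and 0 rose (22 adjusted over the list alone). With TMM or upper-quartile factors 19 fell, and with DESeq2 size factors from the listed rows 15 fell. All 23 were lower by value under each scaling. Inhba, which encodes an activin subunit, fell 14.8-fold, Lpl, which encodes lipoprotein lipase, 4.67-fold, the secreted protein gene Dkk3 3.16-fold and the growth factor gene Ptn 2.87-fold. The homeobox gene Cux1 fell from 8156 ± 514 to 5094 ± 306 (log2 fold change -0.68, SE 0.10, limma adjusted p = 0.0013). Cux2, the remaining member, had 16561 and 15674 normalized counts in the wild types of litter m1, 9437 in the wild type of litter m2 and between 9815 and 10717 in the mutants (log2 fold change -0.39, limma adjusted p = 0.0886), and its difference within litter m2 was 0.12. Without wild type replicate 3 Cux2 passed (limma adjusted p = 0.000163, over 22 alternatives between that and 1). Against the other listed rows the list was lower (camera adjusted p = 1.47e-05), which did not hold with an estimated correlation (adjusted p = 0.306 with an estimated correlation).

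Genes of subcerebral neurons, the deep-layer cells that project to the brainstem and spinal cord, moved mostly the other way. Of 20 genes 13 were listed, and 10 rose and 3 fell (13 adjusted over the list alone). Bcl11b, which encodes the zinc-finger factor Ctip2, rose 2.64-fold, from 10759 ± 825 to 28436 ± 2609 normalized counts (SE of log2 fold change 0.11, limma adjusted p = 6.35e-05), Crym, a thyroid hormone-binding protein gene, 5.54-fold, the axon guidance gene Ntng1 3.96-fold and Lix1 2.88-fold. Fezf2, which specifies these neurons, fell from 4681 ± 88.7 to 3210 ± 181 (log2 fold change -0.55, SE 0.10, limma adjusted p = 0.00341), as did Otx1 (-1.17, and -0.79 within litter m2) and Etv1 (-0.85, and -0.34 within litter m2), named after their values were seen. The wild types of litters m2 and m1 differed by -0.77 in Etv1, which did not pass in litter m2 only (limma adjusted p = 0.0933, between 4.30e-05 and 0.142 over 22 alternatives). Fezf2 did not pass with DESeq2 size factors from the listed rows (limma adjusted p = 0.254, over 22 alternatives between 1.33e-05 and 0.254), nor did Cux1 (0.106, between 3.27e-07 and 0.106). The camera adjusted p for the list was 0.00311, and 0.306 with an estimated correlation.

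**Figure D2:**
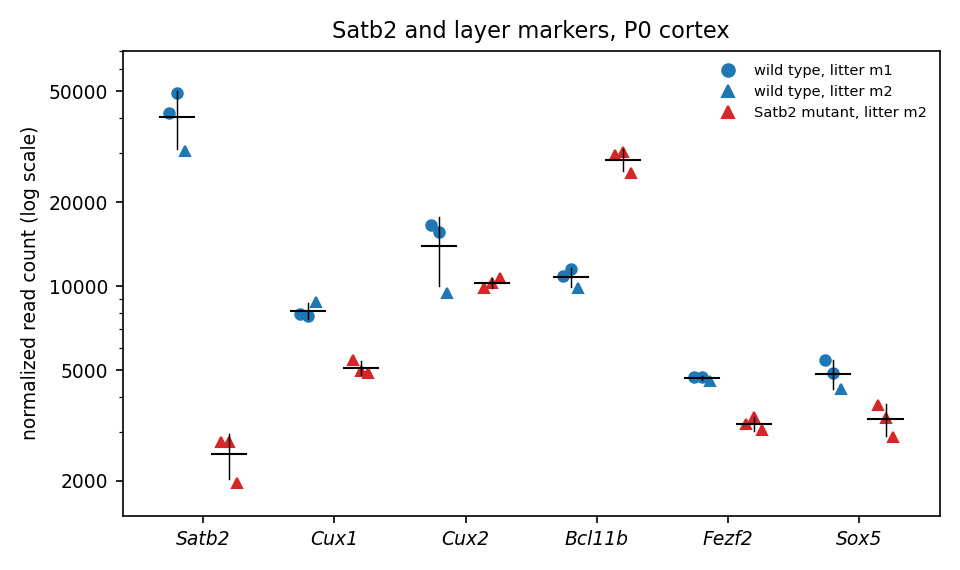
Normalized read counts on a log axis for Satb2 and 5 layer markers, 1 point per library, with the mean of each group as a horizontal line and its SD as a vertical line (n = 3). Circles are litter m1 and triangles litter m2; Satb2 falls from a mean of 40646 to 2493 and Bcl11b rises from 10759 to 28436, while the litter m2 wild type lies at the mutant level for Cux2 only.

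Among genes of corticothalamic neurons, 9 of 16 were listed and 7 fell and 2 rose (9 adjusted over the list alone). Foxp2, a forkhead factor gene, fell 2.72-fold, Syt6, a synaptotagmin gene, 2.62-fold and the transcription factor gene Nfia 1.64-fold, while Crym rose. Sox5 had 4857 ± 583 normalized counts in wild type and 3326 ± 439 in mutant cortex (limma adjusted p = 0.0111), but 0.068 with litter as a term (log2 fold change -0.55 pooled and -0.37 within litter m2). It did not pass with any of the 3 scalings computed from the listed rows (up to 0.282, and between 0.00136 and 0.282 over 22 alternatives). Tbr1 and Bhlhe22 were not analysed here. Of 15 subplate genes 5 were listed, and 4 fell and 1 rose (5 adjusted over the list alone): the netrin receptor gene Unc5c fell 14.3-fold, Cplx3, a complexin gene, 2.50-fold, and Nxph4, which encodes a neurexophilin, 1.84-fold. Kcnab1 fell 1.87-fold, with a log2 fold change of -0.90 pooled and -0.53 within litter m2 and an adjusted p of 0.144 in limma with litter as a term (between 0.00134 and 0.201 over 22 alternatives). Without mutant replicate 1 the adjusted p was 0.053 for Kcnab1 and 0.064 for Cplx3. With DESeq2 size factors from the listed rows 1 subplate gene fell: Cplx3, Nxph4 and Kcnab1 did not pass (limma adjusted p = 0.0865, 0.0555 and 0.0593). Tmem163, named after its values were seen, was the member that rose, with 730 normalized counts in wild type replicate 1, 7877 and 8817 in the others and between 15501 and 15837 in the mutants. Its log2 fold change was 2.08, but 0.83 within litter m2 (adjusted p = 0.478 in limma with litter as a term) and 0.91 without wild type replicate 1 (0.001). Tmem163 did not pass in edgeR (adjusted p = 0.0695) or without any single mutant library (limma adjusted p between 0.0894 and 0.0962), and its adjusted p lay between 0.001 and 0.575 over 22 alternatives. Of 12 Cajal-Retzius genes 6 were listed, and 5 rose and 1 fell (6 adjusted over the list alone): Lhx1 rose 5.15-fold, Trp73 2.42-fold and Ebf3 2.10-fold, all transcription factor genes, and the chemokine receptor gene Cxcr4 fell 2.32-fold. Camera gave adjusted p = 0.391 for the corticothalamic, 0.35 for the subplate and 0.0363 for the Cajal-Retzius list. The last was 0.306 with an estimated correlation and 0.0629 with litter as a term, and between 0.0014 and 0.696 over its alternatives.

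Axon guidance genes changed in both directions. Of 72 genes 31 were listed, and 11 rose and 18 fell (29 adjusted over the list alone). The balance depended on the scaling: 11 rose and 10 fell with TMM and upper-quartile factors, and 11 rose and 8 fell with DESeq2 size factors from the listed rows, which moved the list median from -0.41 to -0.05. Within litter m2 the list median was -0.12 and the list mean -0.001, against -0.41 and -0.20 pooled. Besides Nrp2 and Unc5c, the ephrin receptor gene Epha4 fell 4.35-fold, from 9873 ± 144 to 2295 ± 416, and the ephrin gene Efna5 fell 3.98-fold. Of 19 genes in the list of classical cadherins, which also holds the atypical Cdh13, 8 were listed, and 3 rose and 5 fell (8 adjusted over the list alone). Cdh7 rose 4.11-fold and Cdh13 2.70-fold, while Cdh6 fell 3.57-fold and Cdh10 3.23-fold. Of 22 genes of cortical area patterning 10 were listed, and 2 rose (Crym and Lix1) and 5 fell, Efna5 and Cdh6 among them (7 adjusted over the list alone), but 3 rose and 3 fell with DESeq2 size factors from the listed rows. Camera found no shift of these lists against the other rows (adjusted p = 0.762, 0.864 and 0.762).

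Genes of neuronal signalling were also divided. Of 44 glutamatergic and synaptic genes 19 were listed, and 9 rose and 10 fell (19 adjusted over the list alone). With TMM or upper-quartile factors 9 rose and 6 fell, and with DESeq2 size factors from the listed rows 9 rose and 5 fell (median log2 fold change -0.05). Slc17a7, a vesicular glutamate transporter gene, rose 2.04-fold, the kinase gene Camk2a 1.90-fold and the AMPA receptor gene Gria1 1.64-fold, while the metabotropic receptor gene Grm2 fell 4.56-fold. The list's median log2 fold change was -0.41 and its mean -0.01, and camera placed it above the other rows, with an adjusted p of 0.512. Of 41 genes for voltage-gated potassium channels and their partners 22 were listed, and 6 rose and 13 fell (19 adjusted over the list alone; camera adjusted p = 0.578), and 7 rose and 8 fell with DESeq2 size factors from the listed rows. Kcnh1 fell 13.7-fold, Kcnh5 8.34-fold and Kcns3 2.91-fold, and Kcnip1 rose 2.40-fold. Of 18 immediate early genes, which neurons switch on with activity, 14 were listed, and 12 rose and 1 fell (13 adjusted over the list alone). Fosb had 2.79 ± 1.11 normalized counts in wild type and 40.8 ± 15.5 in mutant cortex, Npas4 rose 5.03-fold, Dusp1 2.06-fold and Junb 1.68-fold. With litter as a term 6 of the 12 that rose still passed. The camera adjusted p for this list was 0.00227, and 0.306 with an estimated correlation.

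Markers of GABAergic interneurons went both ways: 13 of 27 were listed, and 5 rose and 7 fell (12 adjusted over the list alone; camera adjusted p = 0.894). With TMM factors 5 rose and 5 fell, and with DESeq2 size factors from the listed rows 5 rose and 2 fell. Npy, which encodes neuropeptide Y, fell 5.77-fold, from 7966 ± 158 to 1387 ± 163, and the transcription factor gene Mafb 1.55-fold, while Sst, the somatostatin gene, rose 2.27-fold. Mafb did not pass with DESeq2 size factors from the listed rows (adjusted p = 0.124 in limma, between 9.15e-07 and 0.124 over 22 alternatives). Of 18 striatal genes 9 were listed, and 3 rose and 4 fell (7 adjusted over the list alone): Foxp1 fell 2.80-fold, Drd1a, a dopamine receptor gene, 2.33-fold and Ppp1r1b 2.20-fold, and Meis2 rose 1.57-fold. Of 16 thalamic genes 4 were listed, and Ntng1 rose, Foxp2 fell and Slc17a6 fell 1.37-fold (2 of 4 passed adjusted over the list alone); Slc17a6 had a log2 fold change of -0.45 pooled and -0.09 within litter m2 (adjusted p = 0.622 in limma with litter as a term), lost the call in 13 of 22 alternatives (adjusted p between 0.00154 and 0.679) and did not pass without any single library other than wild type replicate 3 (between 0.0708 and 0.155). Of 15 hippocampal genes 12 were listed, and 5 rose and 6 fell (11 adjusted over the list alone): Neurod1 rose 2.17-fold and Nr3c2, the mineralocorticoid receptor gene, 1.88-fold, while Grp fell 30.7-fold and Man1a 2.20-fold. Camera gave adjusted p = 0.762 for the striatal, 0.762 for the thalamic and 0.864 for the hippocampal list. The hippocampal list had a median log2 fold change of -0.55 and a mean of -0.45, but lay above the other rows in camera.

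Markers of microglia and macrophages, the immune cells of the brain, were higher in the mutants. Of 15 genes 12 were listed and 12 rose (12 adjusted over the list alone), and 12 passed with litter as a term. The lysosomal gene Cd68 rose 5.01-fold, from 24.2 ± 2.85 to 127 ± 27.5, the receptor gene Trem2 3.27-fold, the complement gene C1qb 2.81-fold and Csf1r, which encodes a growth factor receptor of these cells, 2.39-fold. The camera adjusted p was 6.72e-06, and 0.306 with an estimated correlation. Of 15 astrocyte genes 8 were listed, and 7 rose and 1 fell (8 adjusted over the list alone): Apoe rose 2.27-fold, Aqp4 2.12-fold and Aldh1l1 1.67-fold, while Sparcl1 rose 1.54-fold (log2 fold change 0.62, and 0.40 within litter m2) with an adjusted p of 0.0696 in limma with litter as a term (between 0.00104 and 0.114 over 22 alternatives). The camera adjusted p was 0.0165, and 0.649 with an estimated correlation. Of 20 radial glia genes 9 were listed, and 6 rose and 0 fell (6 adjusted over the list alone). The mean log2 value of the 9 genes was 10.91 in mutant replicate 2, near the 10.84 of the highest wild type, against 11.36 and 11.60 in the other mutants. Within litter m2 it differed by 0.69 (95% interval -0.06 to 1.45, limma adjusted p = 0.0938). Hopx rose 2.42-fold, the Notch target gene Hes5 1.86-fold, Slc1a3 1.49-fold and Dbi 1.49-fold, the last with a log2 fold change of 0.575 pooled and 0.550 within litter m2 and an adjusted p of 0.0525 in limma with litter as a term (between 0.00245 and 0.222 over 22 alternatives). Slc1a3 did not pass without mutant replicate 1 or 3 (limma adjusted p = 0.0525 and 0.0603). The camera adjusted p was 0.0231, and 0.694 with an estimated correlation.

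Of 13 genes of the oligodendrocyte lineage 6 were listed, and 2 rose and 4 fell (6 adjusted over the list alone; camera adjusted p = 0.746). The progenitor genes Gpr17, Pdgfra and Olig2 fell 2.80-fold, 1.86-fold and 1.87-fold, and the myelin gene Mbp rose 1.68-fold. Of 18 endothelial and pericyte genes 4 were listed and 4 fell (4 adjusted over the list alone; camera adjusted p = 0.336). Cspg4 fell by a log2 fold change of 0.97, Kdr by 0.49, Rgs5 by 0.48 and Pecam1 by 0.36. Kdr, Rgs5 and Pecam1 did not pass with any of the 3 scalings computed from the listed rows, nor without single libraries (limma adjusted p up to 0.0628, 0.0524 and 0.103), and over 22 alternatives their adjusted p reached 0.547, 0.496 and 0.999. Of 15 genes of intermediate progenitors 7 were listed, and 3 rose and 1 fell (4 adjusted over the list alone; camera adjusted p = 0.213): Rhbdl3 rose 3.42-fold, Neurod1 2.17-fold and Btg2 1.63-fold, and Sstr2 fell 2.39-fold. Btg2 did not pass without mutant replicate 1 or 3 (limma adjusted p = 0.0501 and 0.0574), nor Sstr2 without mutant replicate 2 (0.0609). Sstr2 did not pass with any of the 3 scalings computed from the listed rows either (limma adjusted p between 0.0542 and 0.105, and between 0.00439 and 0.341 over 22 alternatives), which leaves 0 of the list lower. Of 30 cell cycle genes 2 were listed, the helicase genes Mcm6 and Mcm4, which fell 1.91-fold and 1.69-fold (2 adjusted over the list alone; Mcm4 log2 fold change -0.76 pooled and -0.33 within litter m2, adjusted p = 0.192 in limma with litter as a term, 0.0905 with DESeq2 size factors from the listed rows and between 0.000763 and 0.255 over 22 alternatives). Without wild type replicate 1 or 2 or mutant replicate 2 Mcm4 had a limma adjusted p between 0.0504 and 0.0579. Of 15 genes of hypoxia and glycolysis 6 were listed, and 5 rose and 0 fell (5 adjusted over the list alone; camera adjusted p = 0.053): Egln3 rose 1.85-fold, the vascular growth factor gene Vegfa 1.55-fold, and Aldoa and Pdk1 1.34-fold each. Pdk1 did not pass without wild type replicate 2 or mutant replicates 1 or 2 (limma adjusted p between 0.0624 and 0.0756), nor with litter as a term (0.0508), where its log2 fold change was 0.40 against 0.42 pooled. Of 13 erythroid genes 2 were listed: Slc25a37 fell 2.02-fold, and Fech had 1304 ± 150 and 1039 ± 165 normalized counts (1 adjusted over the list alone), passing only without wild type replicate 3 (limma adjusted p = 0.0189). With DESeq2 size factors from the listed rows Slc25a37 did not pass either (log2 fold change -0.66, limma adjusted p = 0.0592, between 0.000915 and 0.0925 over 22 alternatives). Of 12 choroid plexus genes Sostdc1 was listed above the low-value limit and rose 3.06-fold (1 adjusted over the list alone). Genes of meningeal fibroblasts and sex-linked genes were not analysed here.

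**Figure D3:**
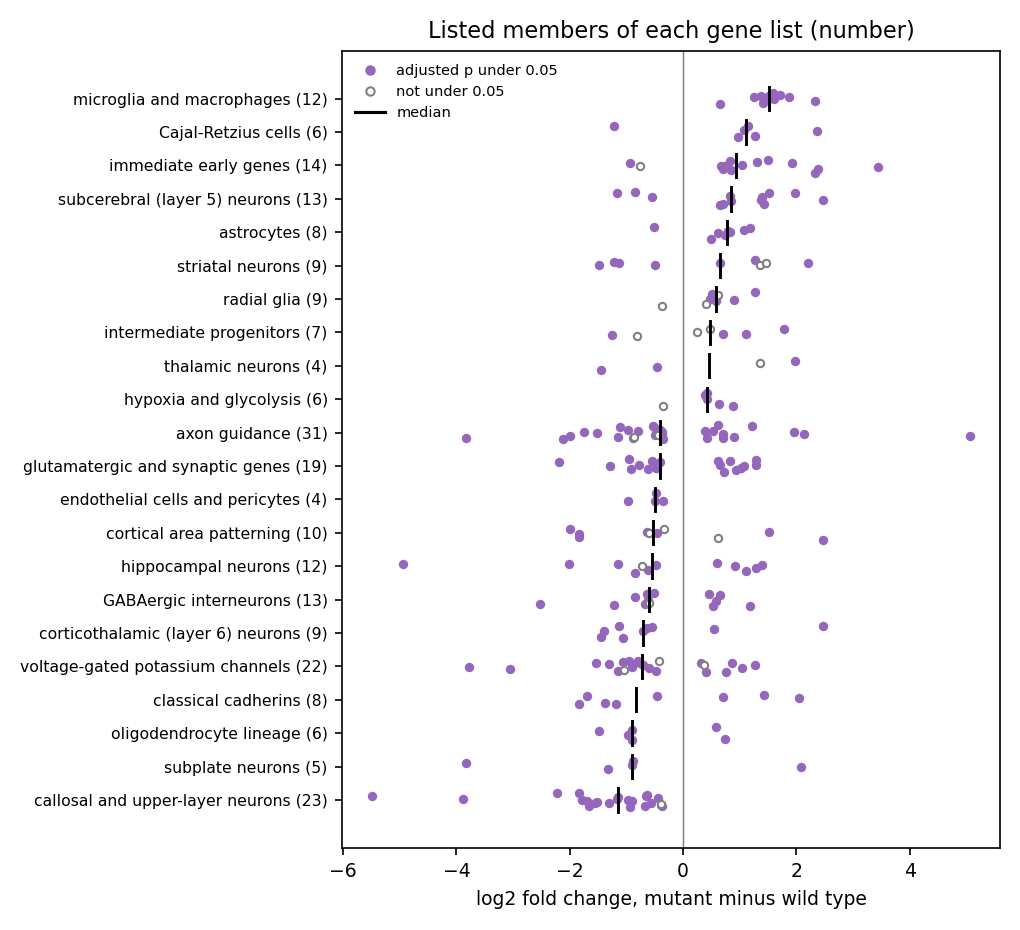
Log2 fold change, mutant minus wild type (x axis), of each listed member of the 22 gene lists with at least 3 listed members (y axis, number listed in brackets). Filled points passed a limma adjusted p of 0.05, open points did not, and black lines are list medians, from 1.52 for microglia and macrophages to -1.15 for callosal and upper-layer neurons.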

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

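The alternatives chosen after seeing the data were TMM scaling, the adjustment over all annotated genes, edgeR with and without litter as a term, Fisher's exact test and the estimated correlation with litter as a term. Satb2 passed in all 23 alternatives run for it, scaling to the total of the listed genes among them, with a log2 fold change between -4.21 and -3.61. Against 3359 genes called in the main test, 2141 were called with litter as a term (908 higher, 1233 lower), 1879 in litter m2 only (807 and 1072), 2239 with DESeq2 size factors from the listed rows (759 lower), 2196 at a limit of 1.5-fold (811 higher), 843 with the adjustment over all annotated genes (291 and 552) and 2165 in edgeR with litter as a term (1255 lower). The genes lower in the mutants numbered 1132 with TMM scaling and 1162 with upper-quartile scaling. These scalings take the listed genes as mostly unchanged, and those were chosen for change. Of the main calls, 2056 were kept with litter as a term and 1813 in litter m2 only. Leaving out 1 library gave between 2184 (828 higher, without mutant replicate 1) and 3705 calls (1400 higher, without wild type replicate 3).

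Cux2 reversed to 0.12 with litter as a term, in litter m2 only and in edgeR with litter as a term, and without wild type replicate 3 its fall passed (log2 fold change -0.65, limma adjusted p = 0.000163). Fech reversed to 0.0259 with DESeq2 size factors from the listed rows. Of 109 named genes, 9 lost the call with litter as a term, 14 with DESeq2 size factors, 6 with TMM and upper-quartile scaling, 27 with the adjustment over all annotated genes, 10 at the limit of 1.5-fold, 7 in edgeR with litter as a term and between 0 and 8 with a library left out. Tmem163 did in edgeR without litter and in DESeq2, and 0 of the 109 did in limma-voom on the recovered reads.

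Camera called 7 lists, 0 with an estimated correlation, with or without litter as a term. Fry, which asks whether a list moves one way and not whether it differs from other genes, called 18. With an estimated correlation the adjusted p was 0.306 for the callosal, subcerebral, Cajal-Retzius, microglial and immediate early lists, 0.694 for radial glia and 0.65 for astrocytes. With litter as a term too it was 0.469 for the callosal and subcerebral lists, 0.696 for the Cajal-Retzius and astrocyte lists, 0.733 for radial glia, 0.634 for microglia and 0.692 for immediate early genes. The subcerebral list lost its call without shared members (0.117) and radial glia in fry (0.0635). The Cajal-Retzius list lost its call with TMM (0.0663), DESeq2 (0.0957) and upper-quartile scaling (0.0641), litter as a term (0.0629), litter m2 only (0.0501) and Fisher's exact test (0.0964). Directions reversed in lists that were not called: axon guidance (adjusted p 0.816) and interneurons (0.79) without shared members, the striatal list with litter as a term (0.951), in litter m2 only (0.922), with litter and an estimated correlation (0.95) and in fry (0.313), and the hippocampal list with DESeq2 scaling (0.900) and in fry (0.0181). The hypoxia list, not called, passed with DESeq2 (0.0493) and upper-quartile scaling (0.0479), a mean of at least 50 (0.0419), without mutant replicate 3 (0.0408) and in fry (0.00112), and its adjusted p reached 0.634 over its alternatives. Apart from the scalings and smaller sets of samples or list members, the cause was not tested. The depth of the whole libraries was not analysed here.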

Other observations

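Gene families were grouped by symbol, and all tests in this part except those of chance between splits and of transcript length and GC were chosen after the results were seen. Zinc-finger genes named Zfp were mostly lower in the mutants: 149 were listed, 11 rose and 121 fell, with a median log2 fold change of -0.76 (direction against the other rows, Fisher's exact test over 8 families, adjusted p = 6.68e-17). Of the related Zbtb genes 19 were listed, 15 fell and 0 rose (median -0.72, adjusted p = 0.0006). Fisher's exact test counts rows of the same 6 libraries as independent, which they are not. Its p-values for these families can therefore be far too small. With litter as a term 64 Zfp and 12 Zbtb genes still fell, and the medians within litter m2 were -0.34 and -0.56; the wild types of litters m2 and m1 differed by -0.44 and -0.32. The medians stayed below 0 under each scaling (-0.40 and -0.36 with DESeq2 size factors from the listed rows). Major histocompatibility genes named H2 went the other way: 7 were listed and 7 rose (median 1.65, adjusted p = 0.00342, median 2.34 within litter m2). H2-Gs10 rose from 29.7 ± 19.7 to 150 ± 37.9 normalized counts and H2-K1 from 127 ± 49.6 to 282 ± 84.3. H2-D1, the row with the highest mean, had 173 and 243 in litter m1, 645 in the wild type of litter m2 and between 924 and 995 in the mutants. Its log2 fold change was 1.65 pooled but 0.55 within litter m2. H2-Q2, H2-Q9 and H2-Q10 had low wild type means of 4.38, 10.6 and 12.8. H2-K1 had a log2 fold change of 1.19 pooled and 1.12 within litter m2, and did not pass with litter as a term (limma adjusted p = 0.0676, over 22 alternatives between 0.00185 and 0.195) or without mutant replicate 3 (0.0519). These genes have near-identical copies, so reads can be split between them. All 7 lie on chromosome 17 between 34132956 and 36258355 (mm9), and the span of H2-Q9 holds those of H2-D1, H2-Q2 and H2-Gs10. The rows are therefore not 7 separate observations. BC023719, named above among the largest rises, lies within the span of H2-T22.

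The real grouping of the 6 libraries called 3359 genes, and it was 1 of 10 splits into 3 and 3; the highest of the other splits called 0. With 10 splits the share is never under 0.1. The rows had also been chosen on the real grouping, which favours it over the other splits, so the splits cannot decide.

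Wild type replicate 3 was the wild type nearest the mutants in 2499 of 3858 genes and the farthest in 893, so that it was nearest in 73.7% of those where it was an extreme; this restates the pattern, and genes of 1 library move together, so a deviation of this library stays open. Removing the trend of the litter difference on transcript length and GC left 62.8% nearest, from 73.6% among the 3372 genes with a length. This argues against the trend as measured here as the whole cause though not as a part of it. Lengths were not those of the unknown annotation used for counting, so some trend may remain and stays open. The genotype difference within litter m2 also followed length (Spearman -0.22 over genes, which are not independent) and GC (0.15). Whether this plays a part in the changes of lists and families was not tested. A mutant Satb2 allele in this animal stays open: its Satb2 was 66.6% of the litter m1 mean, between the 52.7% of 1 mutant allele and the 91.6% of the lower litter m1 library. The 100 most changed genes lay a median 4.76% of the way to the mutants in it, against 31.6% for the others, which goes against that allele but does not decide, since a change averaged over this library ranks highest the genes in which it lies far from the mutants. Litter, this animal and its library cannot be told apart with 1 wild type in litter m2, so the genotype difference and the litter difference may be mixed in genes such as Cux2.

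Microglial and macrophage genes were higher in the mutants, with a median log2 fold change of 1.52 over 12 genes. A lower share of neurons would raise markers of every other cell type alike: the astrocyte list (median 0.77, 7 of 8 higher) goes with it, and radial glia (median 0.57, 6 of 9 called higher) do so less clearly (list mean within litter m2 0.69, 95% interval -0.06 to 1.45, with mutant replicate 2 near the wild types). The 4 endothelial and pericyte genes listed had a median of -0.489, and the highest upper 95% bound among them (-0.04) lay below the lowest microglial change (0.65), which argues against it as the whole cause. The endothelial falls depended on the scaling: Kdr, Rgs5 and Pecam1 did not pass with factors computed from the listed rows. The 6 oligodendrocyte lineage genes listed, with Cspg4 shared with those 4, had a median of -0.90 (4 lower, 2 higher), which goes against it as well. Assuming that the 1 wild type library of litter m2 varies like the other groups, the litter difference is argued against as the whole cause too: the mean of the list was higher by 1.54 within litter m2 (limma with litter as a term on list means, 95% interval 1.04 to 2.05, adjusted p = 0.00365 over 22 lists), and 12 of 12 members passed with that term. The mean log2 value of the list was 6.75 and 6.84 in the wild types of litter m1, 6.77 in that of litter m2 and between 8.06 and 8.49 in the mutants. This argues against a deviation of the 1 wild type animal in litter m2 as the cause, unless it offset a litter difference of like size. A part played by neuron share, and whether there may have been more of these cells or a change in their state, stay open.

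Immediate early genes were higher in the mutants: 12 of 14 listed rose. The mean of the list was higher by 0.846 within litter m2 (limma with litter as a term on list means, 95% interval 0.43 to 1.26). The mean log2 value of the list was 8.28 in the wild type of litter m2 and between 8.93 and 9.29 in the mutants. This argues against the litter difference as the whole cause if the 1 wild type library of litter m2 varies like the other groups. It may be a part, since the wild types of the litters differed by a median of 0.51 over the 14, against 0.84 between genotypes within litter m2. A deviation of the 1 wild type animal in litter m2 stays open, and handling of single pups was not tested and could act on the whole list.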
